A study of Mus musculus with 18 samples.

How the data were processed

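Brains of 6 male C57BL/6 mice aged 8 weeks were studied, 3 wild-type (WT) and 3 carrying a knockout (KO) of Ftsj1, an X-linked gene for an enzyme that methylates the ribose of tRNA anticodon loops. Per the labels' protocols, the dissected brains were frozen in liquid nitrogen and lysed. Lysates went either to ribosome profiling, in which the mRNA fragments held inside ribosomes are sequenced, or to purification of total RNA and selection of polyadenylated RNA. Each mouse gave 3 libraries, which makes 18 samples: total mRNA on a HiSeq, ribosome-contained mRNA on a HiSeq, and ribosome-contained mRNA on a MiSeq. The labels number the mice within each genotype, so the replicates are separate animals, with n = 3 per genotype and library kind.

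For the 12 HiSeq libraries, the authors deposited raw counts of reads per RefSeq transcript accession: the values are whole numbers with a different sum in each library, and the rows and columns are named per the file headers. For the 6 MiSeq libraries, they deposited raw counts, again whole numbers, of ribosome footprints for each codon lying in the ribosomal A site, the position where the incoming aminoacyl-tRNA binds, per the file headers. The column names of both tables give the genotype, the mouse number and the RNA kind but not the instrument, so the ribosome columns were assigned to HiSeq or MiSeq libraries from the names of the tables. The submitters' processing notes name Bowtie2, HISAT2 and HTSeq and the mouse build mm10, with no version or role. How the A site was placed within a footprint, whether reads were counted by strand, and how reads that match several transcripts were treated are not given in the sources used here. No per-sample column was left unused, and the values were analysed as deposited.

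The transcript table held 106519 rows, of which 31089 had at least 1 count. Accessions were matched to gene symbols with a RefSeq gene table of assembly GRCm38, the build that mm10 names. This matched 86040 rows, 45538 of them by accession and version, and the matched rows held 98.0% of all counts. Among protein-coding genes with 1 accession, 39.5% had at least 120 counts over the 12 libraries, against 24.7% of those with 2 accessions and 12.6% of those with 3 or more. Genes with 1 accession held 88.1% of the counts. Genes with several transcript models were thus largely unmeasured, and a low or absent count for such a gene does not bound its expression. Each row was tested as deposited, and summing the accessions of a gene was an alternative. Named genes that overlap another gene in that table are reported as such because the counting could split or mix their reads; paralogs and pseudogenes elsewhere in the genome were not searched.

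Total counts per library ran from 2024748 to 3459406 in total mRNA and from 1055741 to 1560192 in ribosome-contained mRNA. The A-site table held 48481 to 70947 counts of sense codons per library; TTT, for example, had between 609 and 892 counts per library. Shares of single libraries are given with Wilson 95% intervals, which cover counting error only because the labels name no molecular identifiers.

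Replicates were compared before use. A chi-square test over rows with at least 10 counts in a pair of libraries gave a statistic per degree of freedom of 1.63 to 2.11 for pairs of the same genotype in total mRNA and 1.50 to 1.76 in ribosome-contained mRNA. For the A-site codons it was 1.24 for WT replicates 1 and 2, 1.14 for KO replicates 1 and 2, and 1.35 to 1.86 for the other 4 pairs. These chi-square tests compare single libraries, with 63 degrees of freedom, and did not pass for the first pair of each genotype. A difference beyond sampling noise was thus not detected in the codon counts of these pairs, which does not exclude one. Since the labels give separate mice and the HiSeq libraries of the same mice did differ, each was kept as a replicate, and a fit with the pair of each genotype summed into 1 sample was added after this was seen.

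Counts were tested with edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3 with limma 3.58.1. Each kind of HiSeq library was fitted alone, with TMM normalization, the edgeR expression filter (minimum count 10, minimum total count 15) and genotype as the term tested. Translation efficiency, the ratio of ribosome-contained to total mRNA, was tested as the interaction of genotype and library kind in 1 model of all 12 HiSeq libraries, over rows that passed the filter in both kinds. The 61 sense codons were fitted with the sum of sense codons as the library size, no filter and no TMM, and the 3 stop codons were left out. Adjusted p-values are Benjamini-Hochberg adjusted p from these models, with a threshold of 0.05. Levels are CPM, normalized counts scaled to a common library size, or percent of sense codons, as mean ± SD over 3 mice, and log2 fold changes are KO over WT with the standard error (SE) of the model. Exact permutation tests are two-sided, and 3 animals against 3 cannot give a p below 0.1.

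Gene lists for pathways and for markers of cell types and brain regions were tested with camera on log2 CPM (prior count 2, preset correlation between genes of 0.01) with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. The estimated form also uses the few residual degrees of freedom of the fit. Its p-values can therefore rise even where the estimated correlation is small. A rotation test, fry, was run beside camera as planned. Lists with at least 3 measured members were tested, which left 16 pathway lists and 17 marker lists in total mRNA and 16 and 15 in the other comparisons. A group of 5 codons read by tRNAs that FTSJ1 or its yeast counterpart modify was tested in the same way on log2 shares (pseudocount 0.5), with its Phe part, its Leu and Trp part and the codons ending in A or T, adjusted over these 4 lists. Codon content came from the longest annotated GENCODE coding sequence of each gene, and genes in the highest 10 percent for each of 6 codon measures were tested against the rest. The groups, tests, lists and a first set of alternatives were fixed before the data were examined.

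Named genes follow a rule fixed at the same time. Up to 12 genes were named per direction among those past the threshold whose 3 KO values all lay on one side of the 3 WT values, by size of fold change, leaving out predicted gene models. Up to 4 members of each list past the threshold were added. Where fewer than 10 genes passed, the 5 with the smallest unadjusted p in each direction were added as not passing. The substrate codons and the 5 largest codon changes in each direction were named. List members that passed when adjusted over their list alone, but not over all rows, were named after their values were seen.

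Alternatives were DESeq2 1.42.0 as the test, its size factors, no filter, leaving out each mouse in turn, a block for the replicate number or the animal, TMM, limma or DESeq2 for codons, the highest 20 percent for codon content, and inclusion of stop codons. Summing accessions, protein-coding accessions alone, codon counts thinned to the smallest library, summed replicates, the alternatives for single codons other than TTT, and leaving out mice or adding a block in the list tests were added after the data were seen. Total and ribosome libraries of the same mouse share an animal, so the block pairs them by design. Their deviations from the group means correlated at 0.0270 to 0.155 across rows, so values with the animal as a block are given where they change a call. The codon content test was run without this block only. WT and KO mice with the same number are different animals.

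The gene and codon fits were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. All genes were given the same coefficient of variation between replicates (0.06, and 0.04 for codons). Each gene comparison had 1 simulated table, and no effect was shared by the libraries of a mouse. The rates below therefore need not hold for rows with another spread. At log2 changes of 0.5, 1 and 2 the total mRNA fit recovered 47.8%, 80.6% and 92.4% of changed genes, the ribosome-contained fit 47.8%, 86.6% and 100%, and the interaction 22.4%, 70.1% and 100%. Unchanged genes made up 4.55%, 6.02% and 3.76% of the calls. In 20 simulated codon tables, 98 of 100 codons changed by 0.4 were called, and 14.8% of the calls fell on unchanged codons. Shares of unchanged codons drop when others rise, but whether this gave those calls was not tested. Figures were drawn with matplotlib 3.10.9 from tables made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.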

Results

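Brain mRNA, ribosome-contained mRNA and the codons under the ribosomal A site were compared between 3 WT and 3 Ftsj1 KO male mice aged 8 weeks. Ftsj1 encodes a tRNA methyltransferase that acts on the anticodon loop of tRNA-Phe and some other tRNAs, and loss of its human counterpart is a known cause of X-linked intellectual disability. Total mRNA libraries held between 2024748 counts (WT replicate 2) and 3459406 counts (KO replicate 3), and ribosome-contained libraries between 1055741 (KO replicate 1) and 1560192 (WT replicate 3). The A-site libraries held between 48481 (KO replicate 2) and 70947 (WT replicate 1) counts of sense codons. The 13 mitochondrially encoded protein genes took 13.1% to 15.2% of the counts in total mRNA and 5.62% to 6.66% in ribosome-contained mRNA. Correlations of log2 CPM between total mRNA libraries lay between 0.980 and 0.986 across rows.

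Ftsj1 lies on chromosome X at 8238668 to 8252406 (GRCm38). Both of its transcript accessions had a count of 0 in each of the 12 HiSeq libraries, WT and KO alike. The knockout could therefore not be checked in these tables, and because reads shared by transcript models of a gene appear not to have been counted, the 0 sets no upper limit on Ftsj1 expression.

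Codons for phenylalanine were more often in the A site in KO brain than in WT brain. TTC made up 1.45% ± 0.0752 of sense codons in WT and 1.97% ± 0.0309 in KO (SD, n = 3 each), a 1.36-fold rise (95% interval 1.28 to 1.44). TTT rose 1.32-fold (95% interval 1.24 to 1.41), from 1.02% ± 0.0275 to 1.35% ± 0.0775. Among the remaining sense codons, the tyrosine codon TAC rose from 1.24% to 1.37%, and the glycine codon GGC and the alanine codon GCC fell, from 2.05% to 1.86% and from 2.54% to 2.34%. This comparison asked whether loss of Ftsj1 alters how often ribosomes sit on codons that its substrate tRNAs read.

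The log2 fold changes were 0.44 (SE 0.0430, adjusted p = 7.22e-11, edgeR quasi-likelihood with Benjamini-Hochberg adjustment) for TTC and 0.40 (SE 0.0482, adjusted p = 1.02e-08, same model) for TTT. Each KO library lay above each WT library for both codons. Shares of TTT ran from 0.997% (Wilson 95% interval 0.921 to 1.08) to 1.05% (0.974 to 1.14) in WT and from 1.26% (1.16 to 1.36) to 1.39% (1.30 to 1.49) in KO. For TTC they ran from 1.40% (1.32 to 1.49) to 1.53% (1.44 to 1.64) in WT and from 1.94% (1.84 to 2.05) to 2.00% (1.88 to 2.13) in KO. The exact permutation p was 0.1 for each codon, the smallest that 3 animals against 3 can give. The balance between them did not pass: TTT made up 41.4% ± 0.711 of Phe codons in WT and 40.6% ± 1.77 in KO (n = 3 each), and the difference in log2 ratio of TTT to TTC, -0.05, did not exceed the spread between mice (exact permutation p = 0.6).

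The other codons of known or likely substrate tRNAs, TTA and TTG for leucine and TGG for tryptophan, did not pass singly. Their log2 fold changes were 0.16 (adjusted p = 0.191, edgeR), 0.13 (adjusted p = 0.0762, edgeR) and 0.02 (adjusted p = 0.871, edgeR). TTG passed without KO replicate 1 (adjusted p = 0.0447, edgeR) and without WT replicate 1 (adjusted p = 0.0360, edgeR), TTA without WT replicate 2 (adjusted p = 0.0319, edgeR), and TGG was at -0.000361 without WT replicate 1. Over all alternatives the log2 fold change of TTG ran from 0.0838 to 0.181 and that of TTA from 0.126 to 0.234. As a group, the 5 substrate codons were higher than the other sense codons (camera adjusted p = 2.87e-05, Benjamini-Hochberg over 4 codon lists, 5 of 5 positive; adjusted p = 0.0570 with an estimated correlation). The Phe codons alone gave camera adjusted p = 1.9e-05 (adjusted p = 0.0343 with an estimated correlation) and the Leu and Trp codons alone adjusted p = 0.120. The list of codons ending in A or T did not pass against those ending in G or C (camera adjusted p = 0.466).

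**Figure D1:**
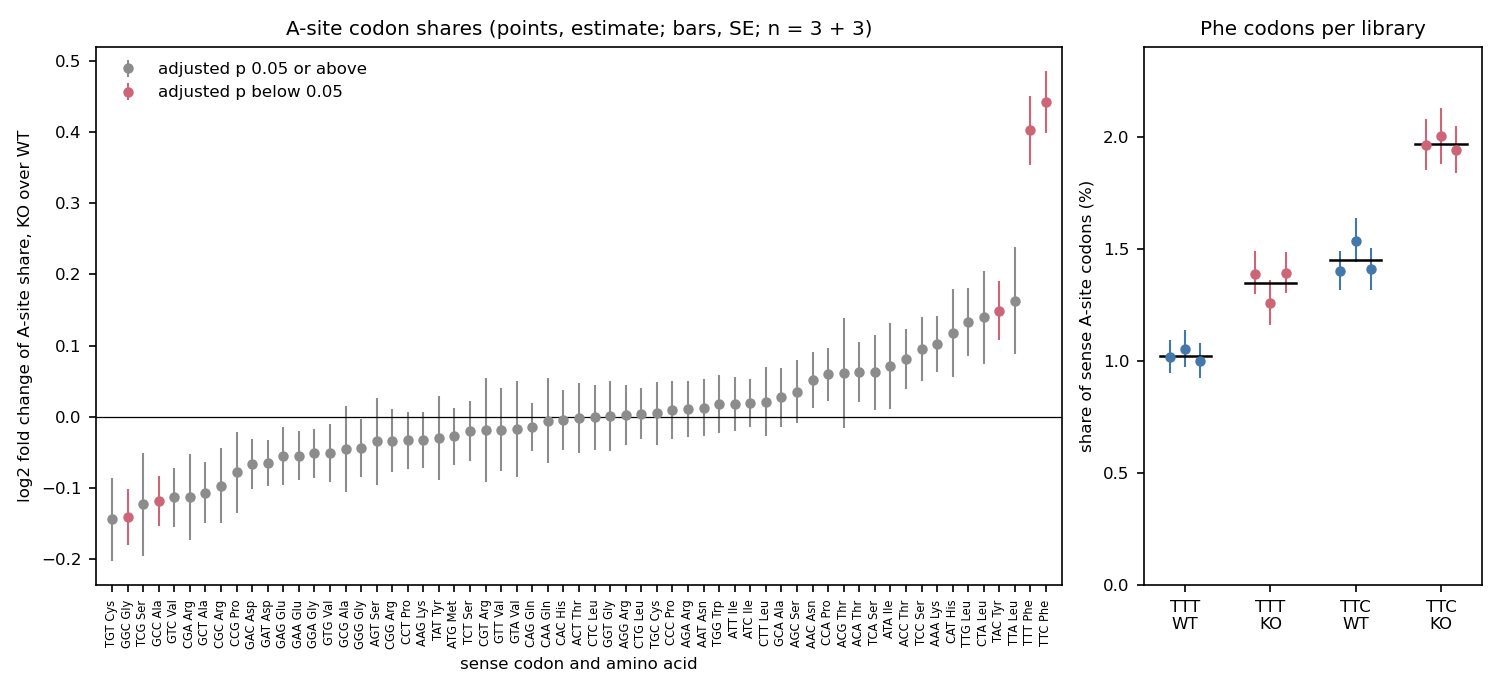
Left, log2 fold change (KO over WT) of A-site share for each of the 61 sense codons, with points as estimates and bars as SE; right, percent of sense codons at TTT and TTC in each library (points, with Wilson 95% intervals as bars; blue WT, red KO; black lines are group means, n = 3). TTC and TTT stand at 0.44 and 0.40, and each KO library lies above the WT libraries for both codons.

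In all, 5 of the 61 sense codons changed, 14 had an unadjusted p under 0.05, and 16 of 61 had KO and WT values that did not overlap, against 10% by chance. The calls for TAC (0.15, SE 0.0417) and GGC (-0.14, SE 0.0392), both with adjusted p = 0.0148 (edgeR), and for GCC (-0.12, SE 0.0350, adjusted p = 0.0203, edgeR) did not hold with each library left out. TAC was lost without KO replicate 1 (adjusted p = 0.0709, edgeR), KO replicate 3 (0.0582), WT replicate 1 (0.0908) or WT replicate 2 (0.0946). GGC was lost without KO replicate 1 (0.130), KO replicate 2 (0.101) or WT replicate 1 (0.0795), and GCC without KO replicate 2 (0.156), KO replicate 3 (0.123), WT replicate 2 (0.0946) or WT replicate 3 (0.117). With KO replicate 2 left out, 3 codons passed in place of 5. Among other named codons, CTA (0.14, adjusted p = 0.191, edgeR), TGT (-0.14, 0.114), TCG (-0.12, 0.295) and GTC (-0.11, 0.0762) did not pass, though TGT did without KO replicate 3 (0.0399) and GTC without KO replicate 1 (0.0497). TCG passed under no alternative and ran from -0.182 to -0.0575. Shares sum to 100%, so a rise of some codons lowers the others. The median log2 fold change of the sense codons other than TTT and TTC was only -0.00480, against -0.14 for GGC and -0.12 for GCC.

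Codon counts of replicates 1 and 2 of each genotype did not differ detectably beyond sampling noise (chi-square p = 0.0928 for WT and 0.213 for KO over the 61 sense and 3 stop codons). The labels give them as separate mice and they are counted as such above. With each such pair counted as 1 sample, TTT (0.41, adjusted p = 0.00950, edgeR) and TTC (0.44, adjusted p = 0.00772, edgeR) rose, and TAC (adjusted p = 0.149), GCC (0.176) and GGC (0.195) did not pass. DESeq2 likewise called TTT and TTC and left TAC (adjusted p = 0.222), GGC (0.218) and GCC (0.314) above the threshold, and limma on log2 shares left TAC and GCC (0.0557 each). GCC was also lost with TMM (adjusted p = 0.0555, edgeR) and TAC with counts thinned to the smallest library (0.0996), while TTG passed with stop codons included (0.0377).

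In total mRNA, Egr1, Ier5, Fosl2 and Bhlhe40 fell in KO brain. Egr1, an immediate early transcription factor (chromosome 18, 34861207 to 34864956, GRCm38), fell from 1394 ± 112 CPM in WT to 1025 ± 62.6 CPM in KO (SD, n = 3 each; log2 fold change -0.44, SE 0.0528, adjusted p = 4.6e-06, edgeR). Ier5, another immediate early gene (chromosome 1, 155096367 to 155099636), fell from 229 ± 24.2 to 156 ± 7.51 CPM (-0.55, SE 0.0714). Fosl2, a subunit of the AP-1 transcription factor (chromosome 5, 32136472 to 32157840), fell from 348 ± 16.1 to 259 ± 16.5 CPM (-0.42, SE 0.0595). Bhlhe40, a transcriptional repressor of the circadian clock (chromosome 6, 108660629 to 108666925), fell from 485 ± 46.1 to 326 ± 32.6 CPM (-0.57, SE 0.0727). Adjusted p was 4.6e-06 for Ier5, 1.09e-05 for Fosl2 and 0.000492 for Bhlhe40 (edgeR). These 4 calls held with each single library left out.

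Across the list of immediate early genes, which does not hold Ier5 or Bhlhe40, 3 of 18 measured members fell (Egr1, Fosl2 and Egr4) and 15 had negative fold changes, with a median of -0.27. Adjusted over the list alone, 6 fell, the others being Dusp6 (-0.23, overlapping a long noncoding RNA gene), Ptgs2 (-0.31) and Fos (-0.33). The list was lower than other genes (camera adjusted p = 0.000118, Benjamini-Hochberg over 33 lists; adjusted p = 0.593 with an estimated correlation). Egr4, a relative of Egr1, fell by 0.40 (adjusted p = 0.0114, edgeR), and Homer1, a gene of excitatory synapses, fell from 80.7 to 58.5 CPM (-0.48, adjusted p = 0.0149, edgeR). The Homer1 value is for 1 of its 4 transcript models. Homer1 was the sole called member of the postsynaptic list, in which 22 of 23 genes did not pass, over all rows or adjusted over the list alone, the median was -0.00 and the mean 0.04 (list adjusted p = 0.948, camera). Egr4 was lost without KO replicate 1 (adjusted p = 0.153, edgeR), KO replicate 2 (0.0648) or WT replicate 1 (0.487), and Homer1 without KO replicate 1 (0.114), KO replicate 3 (0.115) or WT replicate 1 (0.495). Markers of neurons (5 of 7 negative, median -0.10) and of cortex (4 of 7 negative, median -0.03) did not pass as lists (camera adjusted p = 0.370 and 0.749). With edgeR 0 of them passed over all rows, and adjusted over the list alone the neuron marker Nefm, a neurofilament gene that overlaps a long noncoding RNA gene, fell (-0.17).

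Ttr, which encodes the thyroid hormone carrier transthyretin and is made in the brain by the choroid plexus, rose from 2237 ± 118 to 2683 ± 7.50 CPM (0.26, SE 0.0443, adjusted p = 0.000492, edgeR; chromosome 18, 20664209 to 20674326). The 5 measured choroid plexus markers were all positive, with a median of 0.26. Of these 1 rose, and adjusted over the list alone 3 did, with the water channel Aqp1 (0.65) and the chloride channel protein Clic6 (0.27) beside Ttr. The list was higher than other genes (camera adjusted p = 0.00123; adjusted p = 0.481 with an estimated correlation), and with the preset correlation it passed without each single library. The estimated correlation was only 0.0154, so the loss of the call does not show that these markers moved together.

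Genes of the unfolded protein response were lower as a list: 14 of 16 were negative, with a median of -0.12 (camera adjusted p = 0.00584; adjusted p = 0.481 with an estimated correlation). With edgeR 0 of the 16 passed singly, and adjusted over the list alone 5 fell, the secreted factor Manf (-0.30), the protein disulfide isomerases Pdia6 (-0.17) and Pdia3 (-0.13), and the chaperone partners Dnajc3 (-0.17) and Sdf2l1 (-0.34). Pdia3 overlaps Catsper2, Pdia6 overlaps Atp6v1c2, and a pseudogene lies inside Dnajc3. The list was lost without KO replicate 3 (camera adjusted p = 0.0591). The other 30 lists had camera adjusted p between 0.0744 and 0.948. Without WT replicate 1, the neighbours of Ftsj1 (adjusted p = 0.00623) and blood cells (0.0112) also passed, so that 5 lists did in place of 3, without KO replicate 1 blood cells (0.0155), and without WT replicate 2 the mitochondrially encoded genes (0.00157).

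Among other named genes, Eef1a2, the translation elongation factor of neurons and muscle (chromosome 2, 181141758 to 181157015), rose from 2279 ± 105 to 2631 ± 13.0 CPM (0.21, SE 0.0439, adjusted p = 0.0113, edgeR). It was 1 of 37 translation factors, and the other 36 did not pass. Adjusted over the list alone, Gcn1 (0.22), which overlaps a microRNA gene, rose as well. The collagen gene Col6a1 rose from 50.2 ± 5.94 to 72.5 ± 8.08 CPM (0.52, adjusted p = 0.0138, edgeR). Rows of predicted transcripts of Tmpo, a nuclear lamina protein (115 ± 15.9 to 176 ± 8.05 CPM, 0.60, adjusted p = 4.6e-06, edgeR), and of Celf2, a splicing regulator (2.11-fold from 7.91 ± 1.96 CPM, 1.08, adjusted p = 0.0149, edgeR), also rose, which speaks only for those transcript models. The inositol transporter Slc5a3 (-0.40), the growth-related Ndrg1 (-0.34), the retinoic acid enzyme Aldh1a1 (-0.33) and the insulin receptor substrate Irs2 (-0.32) fell, with adjusted p between 0.00171 and 0.0149 (edgeR). The microRNA genes Mir128-2 (-0.95, adjusted p = 0.0188, edgeR) and Mir139 (-0.68, adjusted p = 0.00446, edgeR) fell, but they lie inside Arpp21 and Pde2a, whose reads cannot be told apart from theirs. Slc5a3 likewise overlaps Mrps6, Tmpo a tRNA gene, and Ttr, Bhlhe40, Irs2, Celf2 and Aldh1a1 long noncoding RNA genes, with a pseudogene also inside Celf2 and Aldh1a1.

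Of the 8206 rows tested in total mRNA, 27 changed, 7 up and 20 down, including 3 rows without a gene match and 3 predicted gene models; 669 had an unadjusted p under 0.05, where chance gives 410. KO and WT did not overlap in 13.3% of rows, against 10% by chance. Tmpo and Ttr kept their calls without each single library. Leaving out KO replicate 1 gave 9 changed rows and ended the calls of Celf2, Col6a1, Eef1a2, Mir128-2, Slc5a3, Ndrg1, Aldh1a1 and Irs2 (adjusted p 0.0561 to 0.293, edgeR). Leaving out WT replicate 1 gave 15 and ended those of Celf2, Col6a1, Mir128-2, Mir139, Aldh1a1 and Irs2 (0.0847 to 0.588). Leaving out WT replicate 2 ended Celf2, Col6a1, Mir128-2, Ndrg1 and Irs2 (0.0801 to 0.117), KO replicate 2 Celf2 and Mir128-2 (0.0721 to 0.115), KO replicate 3 Eef1a2, Mir128-2, Ndrg1 and Irs2 (0.106 to 0.115), and WT replicate 3 Eef1a2 (0.161). Without WT replicate 3, 42 rows changed. DESeq2 did not call Homer1 or Irs2 (adjusted p = 0.0550 each), nor Celf2 or Mir128-2, for which it gave no adjusted p. Eef1a2 was lost with no filter on low counts (adjusted p = 0.103, edgeR), where 43 rows changed.

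In ribosome-contained mRNA, 8 of the 10 calls were genes also called in total mRNA. Ttr rose from 4937 ± 284 to 6578 ± 356 CPM (1.33-fold; SD, n = 3 each; log2 0.41, SE 0.0464, adjusted p = 3.7e-06, edgeR), and Eef1a2 from 4740 ± 123 to 5399 ± 92.9 CPM (0.19, SE 0.0410, adjusted p = 0.0412, edgeR). Bhlhe40 fell from 710 ± 86.0 to 444 ± 25.1 CPM (-0.67, SE 0.0760, adjusted p = 2.57e-05, edgeR), Egr1 from 2154 ± 172 to 1541 ± 125 CPM (-0.48, SE 0.0597, adjusted p = 0.000102, edgeR) and Ier5 from 229 ± 31.6 to 143 ± 19.8 CPM (-0.67, SE 0.109, adjusted p = 0.00156, edgeR). Fosl2 (-0.47, adjusted p = 0.0452, edgeR), Irs2 (-0.42, 0.00616) and Slc5a3 (-0.39, 0.0122) also fell. The remaining calls were Nr1d1, a repressor of the circadian clock (chromosome 11, 98767932 to 98775377), which fell from 384 ± 8.86 to 266 ± 51.1 CPM (-0.53, SE 0.0951, adjusted p = 0.0122, edgeR), and the vault RNA gene Vaultrc5 (chromosome 18, 36801763 to 36802107; 1005 to 767 CPM, -0.39, adjusted p = 0.0104, edgeR).

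Nr1d1 overlaps Thra, and strand use is not given. Vaultrc5 is a noncoding RNA gene, so its reads do not measure translation. In total mRNA, Nr1d1 was at -0.43 (adjusted p = 0.696, edgeR) and Vaultrc5 at -0.25 (adjusted p = 0.838, edgeR). Of the 27 rows called in total mRNA, 21 were tested here, 19 with the same sign, and 8 were called in both: Bhlhe40, Egr1, Eef1a2, Fosl2, Ier5, Irs2, Slc5a3 and Ttr. All 10 rows called here had the same sign in total mRNA. Independent lists of these sizes would share 0.0456 rows among the 4601 tested in both, though lists from the same animals are not independent. Among the rows called in total mRNA that did not pass here were Egr4 (-0.41, adjusted p = 0.187, edgeR), Ndrg1 (-0.34, 0.0843), Homer1 (0.10, 0.966), Aldh1a1 (-0.10, 0.785), Col6a1 (0.09, 0.938) and Tmpo (-0.18, 0.798).

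**Figure D2:**
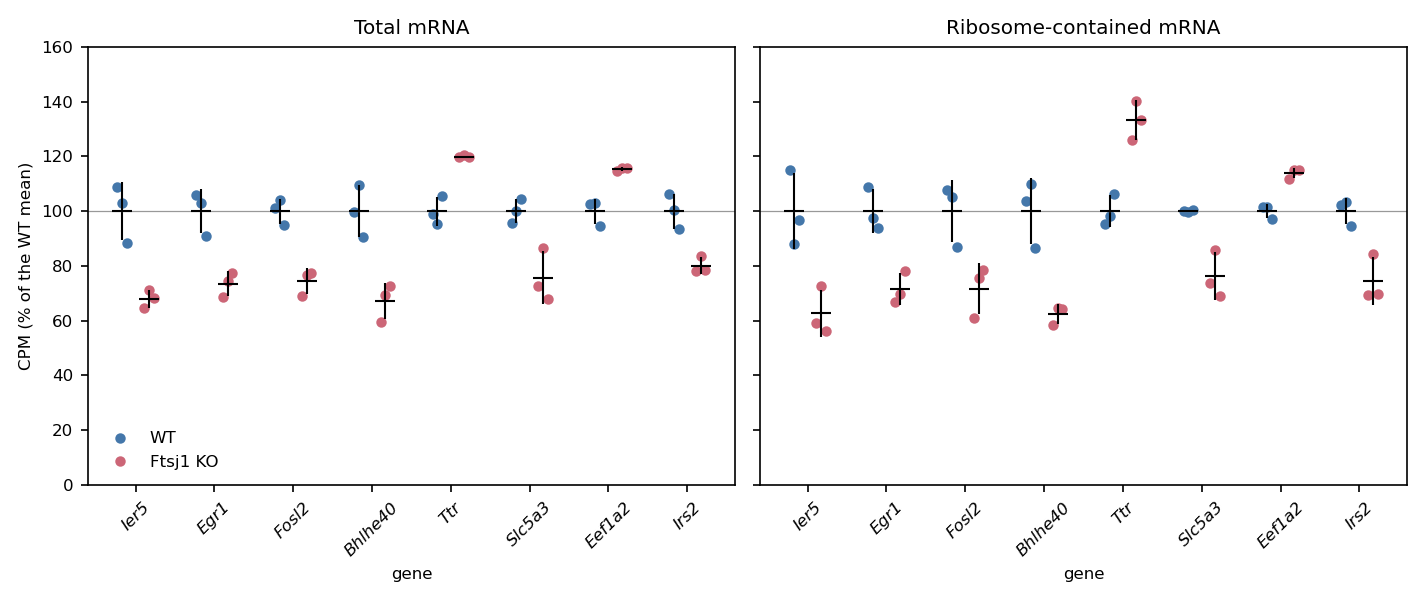
CPM as percent of the WT mean for the 8 genes called in both total and ribosome-contained mRNA (points are libraries, black dashes group means, bars SD, n = 3 per genotype). Ttr and Eef1a2 lie above the WT mean in KO in both kinds of library, and Bhlhe40, Ier5, Egr1, Fosl2, Slc5a3 and Irs2 below it.

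In all, 10 of 4749 rows changed, 2 up and 8 down; 450 had an unadjusted p under 0.05, where chance gives 237, and groups did not overlap in 14.7% of rows, against 10% by chance. Bhlhe40, Egr1 and Ttr kept their calls without each single library. Without WT replicate 1, 4 rows passed and Ier5, Nr1d1, Fosl2, Irs2, Slc5a3 and Eef1a2 did not (adjusted p 0.0643 to 0.391, edgeR). Without WT replicate 2, 5 passed, 1 of them the minor spliceosome RNA gene Rnu12 (0.51, adjusted p = 1.33e-06, edgeR), named after its value was seen, and Nr1d1, Fosl2, Irs2, Vaultrc5, Slc5a3 and Eef1a2 did not (0.0547 to 0.183). Eef1a2 was lost without any 1 of the 6 libraries (0.0525 to 0.174), Fosl2, Irs2 and Slc5a3 also without KO replicate 1 (0.0888 to 0.286), Nr1d1 without KO replicate 2 (0.0509), and Fosl2, Irs2, Vaultrc5 and Slc5a3 without KO replicate 3 (0.0543 to 0.143). Without WT replicate 3, and likewise without KO replicate 2, 24 rows passed. Fosl2 (adjusted p = 0.265), Slc5a3 (0.112) and Eef1a2 (0.0888) did not pass with DESeq2, Fosl2 with DESeq2 size factors (0.0508, edgeR), or Eef1a2 with no filter (0.0613, edgeR), where 27 rows passed.

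Immediate early genes were again lower as a list: 2 of 14 fell (Egr1 and Fosl2) and 13 were negative, with a median of -0.32 (camera adjusted p = 2.59e-05; adjusted p = 0.559 with an estimated correlation). Adjusted over the list alone 8 fell, among them Junb (-0.32), Fos (-0.42) and Sik1 (-0.54), which overlaps a long noncoding RNA gene. Neuron markers were negative in 4 of 5 cases, with a median of -0.07 (camera adjusted p = 0.266), and cortex markers in 2 of 5, with a median of 0.02 (camera adjusted p = 0.905). With edgeR 0 of these passed over all rows, and adjusted over the list alone the neurofilament genes Nefm (-0.18) and Nefl (-0.12) fell. Choroid plexus markers were higher, with 1 of 5 up (Ttr), all 5 positive and a median of 0.41 (camera adjusted p = 0.00115; adjusted p = 0.486 with an estimated correlation), and adjusted over the list alone all 5 rose, with Sostdc1 at 0.60, Aqp1 at 0.66, Kl at 0.33 and Clic6 at 0.27. Unfolded protein response genes were lower, with 14 of 14 negative and a median of -0.15 (camera adjusted p = 0.00196; adjusted p = 0.581 with an estimated correlation). With edgeR 0 of them passed, singly or adjusted over the list alone.

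The 13 mitochondrially encoded genes were all positive, with a median of 0.13 (camera adjusted p = 0.00196; adjusted p = 0.817 with an estimated correlation). With edgeR 0 passed over all rows, and adjusted over the list alone 8 rose, led by mt-Cytb (0.18) and mt-Co3 (0.17). Cytosolic ribosomal proteins were positive in 26 of 35 cases, with a median of 0.08 (camera adjusted p = 0.0136; adjusted p = 0.774 with an estimated correlation) and 0 passing over all rows or over the list alone. The mitochondrial list was lost without WT replicate 2 (camera adjusted p = 0.0543) or KO replicate 2 (0.132). The ribosomal protein list was lost without WT replicate 1 (0.122), WT replicate 3 (0.0767), KO replicate 2 (0.0774) or KO replicate 3 (0.271), so that 3 lists passed without KO replicate 2 in place of 5. The other 26 lists had camera adjusted p between 0.122 and 0.905, with axon guidance genes passing without KO replicate 1 (0.0254). Of 34 translation factors, Eef1a2 rose and 33 did not pass, over all rows or adjusted over the list alone.

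**Figure D3:**
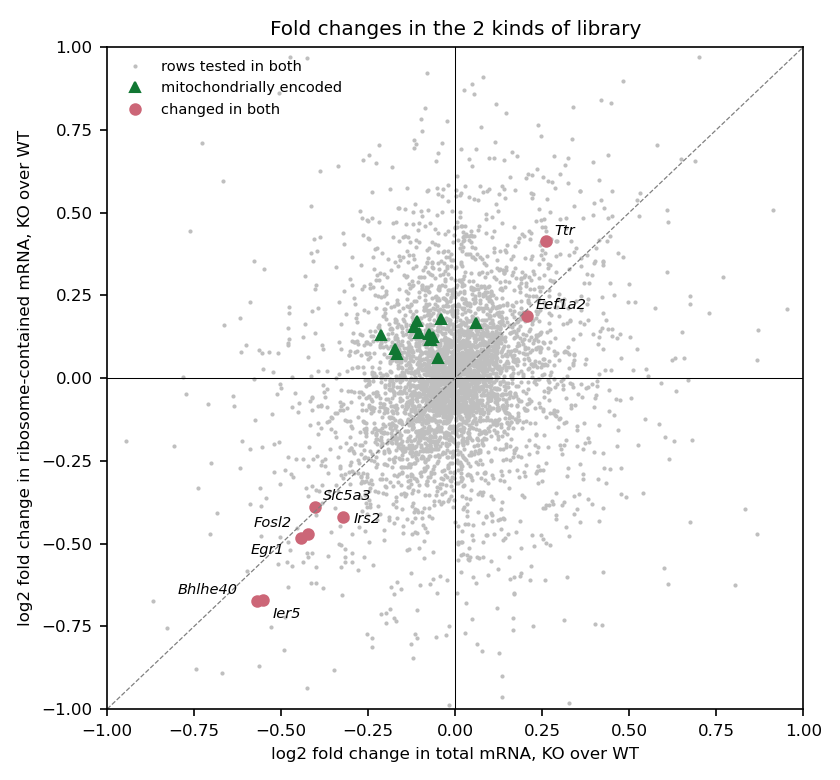
Log2 fold change (KO over WT) in total mRNA (x axis) against ribosome-contained mRNA (y axis) for rows tested in both (grey), with mitochondrially encoded genes as green triangles, rows changed in both in red and equal change as the dashed line; 27 of the 4601 rows lie outside the axes. The 8 rows changed in both lie near the dashed line, and the mitochondrially encoded genes lie above it.

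Translation efficiency, tested as the ratio of ribosome-contained to total mRNA, changed for 0 of 4601 rows with edgeR and for 0 with DESeq2; 228 had an unadjusted p under 0.05, where chance gives 230. None of the genes that changed in both kinds of mRNA passed this test: Bhlhe40, Egr1, Eef1a2, Fosl2, Ier5, Irs2, Slc5a3 and Ttr had adjusted p between 0.960 and 0.998 (edgeR). The smallest adjusted p was 0.121 (edgeR), for the predicted-transcript row of Tmpo (-0.78, SE 0.172) and for Nova2, a neuronal splicing factor (-0.31, SE 0.0697; chromosome 7, 18925888 to 18965319). Other genes with the smallest unadjusted p, none passing, were mt-Co3 (0.28), Mrps33 (1.84), Dusp18 (1.43), Rpl10 (1.21), Ensa (0.73), Rn7sk (-0.52), Htt (-1.43) and Ncan (-0.83). Their adjusted p lay between 0.235 and 0.542 (edgeR), and Rpl10, like other ribosomal protein genes, has pseudogene copies with which the counting could share reads. Dusp18 overlaps 4921536K21Rik, Nova2 a long noncoding RNA gene, Ncan a microRNA gene and Rpl10 a small nucleolar RNA gene. Rn7sk is a noncoding RNA gene, for which the ratio does not measure translation. The log2 ratio itself was low for Ensa (mean -4.60 in WT and -3.92 in KO) and Htt (-4.82 and -6.32), and KO and WT ratios overlapped for Htt.

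With the animal as a block, which pairs the libraries of each mouse, 4 rows changed and 298 had an unadjusted p under 0.05. They were mt-Co3 (0.28, SE 0.0526, adjusted p = 0.00745, edgeR), mt-Nd1 (0.27, SE 0.0462, adjusted p = 0.000656, edgeR), Nova2 (-0.31, SE 0.0621, adjusted p = 0.00617, edgeR) and Tmpo (-0.79, SE 0.161, adjusted p = 0.00650, edgeR); mt-Nd1 was named after its value was seen. Without a block, 4 rows passed without KO replicate 1: Rpl10 (adjusted p = 0.0292, edgeR), Rn7sk (0.0292), Htt (-2.31, 0.0337) and Rpl41 (2.15, 0.0106). Without WT replicate 2, Rnu12 alone passed (0.68, adjusted p = 2.87e-05, edgeR), and with no filter on low counts Rnu12 (0.52, adjusted p = 4.34e-05, edgeR) and Tmpo (0.0269) did. Rpl41 and Rnu12 were named after their values were seen, and Rnu12, like Rn7sk, is noncoding.

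As a list, the 13 mitochondrially encoded genes had a higher ratio in KO: all 13 were positive, with a median of 0.22, and with edgeR 0 passed over all rows. Adjusted over the list alone 4 rose, mt-Co3 (0.28), mt-Atp6 (0.24), mt-Cytb (0.22) and mt-Co1 (0.18). With the preset correlation between genes, the camera adjusted p was 1.4e-05 without the block and 7.9e-05 with it. The correlation estimated between these genes was 0.862 without the block. With an estimated correlation the call was lost (adjusted p = 0.896, and 0.753 with the block). It was also lost without WT replicate 1 (camera adjusted p = 0.124), which left 0 lists. In total mRNA, 12 of the 13 were negative, with a median of -0.07 (camera adjusted p = 0.103). These mRNAs are translated inside mitochondria, by ribosomes other than those of the cytosol. The other 30 lists had camera adjusted p between 0.249 and 0.942.

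To ask whether genes rich in substrate codons changed in translation efficiency, 4011 genes were ranked by codon content. With camera 0 of 6 sets, for TTT, TTC, TTA, TTG, TGG and codons ending in A or T, differed from other genes. The test was run without the animal as a block, so whether pairing the libraries of each mouse changes this was not tested. The 403 genes in the highest 10 percent for TTT had a median log2 change of 0.02 against 0.00 in the rest (camera adjusted p = 0.359), and no set had a smaller adjusted p. The highest 20 percent likewise gave 0 sets.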

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

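The tests of neuron and cortex markers, of other choroid plexus markers and of T-rich codons, the separate values of the 2 parts of the clock score, the splits with the animal as a block, and the list tests that leave out a mouse or add a block, were chosen only after the results they bear on were seen. The remaining tests in this part were written before.

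The median log2 fold change of the 13 mitochondrially encoded genes was 0.13 in ribosome-contained and -0.07 in total mRNA. The list test of the interaction passed only with the preset correlation between genes (camera adjusted p = 1.4e-05). The correlation estimated between these genes was 0.862, and with it the list did not pass (camera unadjusted p = 0.151, adjusted p = 0.896). The 13 genes thus moved largely together and are not 13 separate observations. Whether the effect of the knockout on the list as a whole differs between the kinds of mRNA is therefore not settled. With the preset correlation, the call was also lost without WT replicate 1 (camera adjusted p = 0.124). Over the 7 runs that added the animal as a block or left out 1 mouse, this adjusted p lay between 3.02e-07 and 0.124. Tested singly over all rows, 0 of the 13 genes passed without the block. With it, mt-Nd1 (0.27, adjusted p = 0.000656, edgeR) and mt-Co3 (0.28, adjusted p = 0.00745, edgeR) passed and the others did not.

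Phe codons rose in the A site of KO footprints: TTT and TTC together were higher by 0.42 on the log2 scale (SE 0.0359). A change in which mRNAs were translated is argued against for the genes that the counts measure. The share of TTT and TTC expected from the ribosome-contained counts and the coding sequences differed by 0.00418 (SE 0.00161). Genes with several transcript models were largely unmeasured, so a shift among their mRNAs could not be seen. The expected level, 3.84% to 3.86%, lay above what was observed (TTT 1.02% and TTC 1.45% in WT), so only its difference between genotypes is used. A bias of the KO libraries shared by T-rich codons in general is argued against too, since the 8 other sense codons with at least 2 T differed by 0.0127 (SE 0.0225). Among them TTA (0.16) and TTG (0.13), which begin with TT as the Phe codons do, were positive without passing. CTT and ATT stood at 0.02 each, and GTT, TAT, TCT and TGT at -0.14 to -0.02. TTA and TTG are also substrate codons, so a bias limited to codons that begin with TT cannot be told apart. An effect of the genotype on decoding of Phe codons stays open. The A-site share is a relative measure of how often ribosomes sit on a codon, and the data hold no absolute dwell time and no measure of tRNA methylation. How the authors placed the A site, and the amount of each tRNA in these brains, were not tested and stay open too.

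Egr1, Ier5, Fosl2 and Bhlhe40 fell in KO in both kinds of mRNA, while the call of the immediate early list, which holds Egr1 and Fosl2, was lost with an estimated correlation (camera adjusted p = 0.593 in total and 0.559 in ribosome-contained mRNA). A smaller share of neurons or cortex in the KO samples is argued against, since the mean of their markers differed by -0.0525 (SE 0.0278), while these genes fell by 0.42 to 0.67. A different hour of sampling could lower Bhlhe40 and Nr1d1, and it cannot be told apart from the genotype, because the score of clock genes, those in phase with Nr1d1 minus those in antiphase, differed by -0.23 with an SE of 0.201; the in-phase part, of 3 genes in total and 2 in ribosome-contained mRNA, differed by -0.0873 (SE 0.0121), less than Bhlhe40 or Nr1d1, and the antiphase part by 0.143 (SE 0.196). A different stress state before sampling likewise cannot be told apart, because glucocorticoid-responsive genes differed by 0.0130 with an SE of 0.148. An effect of the genotype on neuronal activity, for which the data hold no separate measure, stays open as untested.

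Ttr was higher in KO by 0.34 (SE 0.0492), averaged over both kinds of mRNA. More choroid plexus in the KO samples is a candidate explanation with the values it needs: the 4 other measured markers, Aqp1, Clic6, Kl and Sostdc1, were higher by 0.377 (SE 0.0308). Choroid plexus is part of the brain, so its most abundant transcript, Ttr, stood at 2237 CPM already in WT total mRNA, and no dissection step that would remove the tissue is in the labels. Higher expression within choroid plexus cells of KO mice would give the same values, so a biological difference stays open as well.

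The 6 animals can be split into 2 groups of 3 in 10 ways, too few for a share of splits under 0.05 in any of the following counts. The real split gave 27 changed rows in total mRNA against at most 2 in another split, 10 against 0 in ribosome-contained mRNA, and 5 codons against 0, and in each case 1 of the 10 splits, the real one, reached its value. For translation efficiency with the animal as a block, the real split gave 4 rows against at most 1 in another, with 298 against at most 244 at an unadjusted p under 0.05, and 1 of the 10 splits reached the 4 rows. Without the block the real split gave 0 rows with edgeR, a count that each of the 10 splits reaches by construction, so this comparison decides nothing; there 228 rows had an unadjusted p under 0.05, and DESeq2 gave 0. The correlation across rows of the fold changes in total and ribosome-contained mRNA was 0.210 in the real split and at most 0.181 in another, so 1 of the 10 splits reached it; genes are not independent replicates.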

How the results depend on the processing

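The fits of summed accessions, of protein-coding accessions, of thinned and of summed codon counts, each alternative for TTC and for single codons other than TTT, and the list tests that leave out a mouse or add a block were chosen only after the data were seen. The rise of TTT (log2 0.37 to 0.44) and of TTC (0.42 to 0.48) passed under each alternative run. The 5 substrate codons, as 1 test, passed with 1 mouse left out (p = 1.27e-06 to 6.14e-05) and with an estimated correlation (p = 0.0285), but with that correlation and adjustment over 4 codon lists they did not (adjusted p = 0.0570). With no filter on low counts, 43 rows changed in total mRNA, 27 in ribosome-contained mRNA and 2 in translation efficiency, where more rows are tested. Leaving out each mouse gave 9 to 42, 4 to 24 and 0 to 4 changed rows, and 3 to 6 codons. DESeq2 gave 21 rows in total mRNA, 7 in ribosome-contained mRNA and 2 codons, limma 3 codons, and summing replicates 1 and 2 gave 2 codons. With the animal as a replicate block, 4 rows changed in translation efficiency and no list call changed. The labels name nothing that WT and KO mice of the same number share. The deviations of same-numbered libraries correlated at -0.0724, 0.0102 and -0.0230 in total mRNA, at 0.0237, 0.0192 and 0.0278 in ribosome-contained mRNA, and at -0.0521, 0.157 and -0.0137 for codons. In ribosome-contained mRNA, pairs with different numbers lay lower, between -0.0252 and 0.0019. A replicate block over these numbers gave 32, 48 and 5 changed rows or codons, and in ribosome-contained mRNA it kept all 10 calls. A batch shared by mice of the same number is therefore not excluded for those libraries. With an estimated correlation 0 lists passed in total mRNA, 0 in ribosome-contained mRNA and 0 in translation efficiency, in place of 3, 5 and 1. Some estimates were small, at 0.0154 for choroid plexus markers in total mRNA and 0.00109 in ribosome-contained mRNA. With fry, that list passed in total mRNA (adjusted p = 0.0441) but not in ribosome-contained mRNA (adjusted p = 0.127). No other list passed with fry. With the preset correlation and 1 mouse left out, 2 to 5, 3 to 6 and 0 to 1 lists passed. The sign of TGG, which did not pass, reversed to -0.000361 without WT replicate 1 and reached 0.0518 without WT replicate 2. Among 56 named genes, codons and lists, 639 values were recomputed: 523 kept sign and side of the threshold, 102 lost a call, 13 gained one and 1 reversed. The 56 include 10 translation efficiency genes and some codons that were not called in the main fits. Those could not lose a call, so the share kept is not that of the called results. Calls held in each alternative for 6 of 17 named genes in total mRNA and 3 of 10 in ribosome-contained mRNA. The cause of these differences was not tested. More rows were tested without the filter, but adjusted p of single rows also moved, both ways. In total mRNA that of Bhlhe40 went from 0.000492 to 6.48e-15 and that of Ttr from 0.000492 to 0.00277 (edgeR). Leaving out a mouse raised some counts and lowered others. The ribosome-contained libraries were shallower, and 4749 rows were tested in them against 8206 in total mRNA; whether depth alone sets this was not tested.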

Other observations

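The lists and genes in this part were tested as planned, except for the list tests that leave out a mouse, which were chosen after the data were seen.

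Genes induced by the transcription factor ATF4 in the integrated stress response did not pass as a list: 9 of 14 were positive in total mRNA, with a median of 0.18, and 7 of 14 in ribosome-contained mRNA, with a median of 0.04. A pair of its members had positive fold changes of 0.70 or more in both kinds of mRNA. Atf5, itself a stress-response transcription factor, was at 1.05 (SE 0.246, adjusted p = 0.0541, edgeR) in total mRNA and at 1.21 (adjusted p = 0.273, edgeR) in ribosome-contained mRNA, in a row of a noncoding transcript model. Nupr1, a stress-induced chromatin protein, was at 0.70 (adjusted p = 0.335, edgeR) and at 1.18 (adjusted p = 0.169, edgeR). KO and WT values did not overlap for either gene in either kind of library. Atf5 overlaps Nup62 and Il4i1b, and Nupr1 a long noncoding RNA gene. Adjusted over the list alone, 2 of the 14 measured members, Atf5 and Nupr1, rose in total mRNA and 3 in ribosome-contained mRNA, where the amino acid transporter Slc7a5 (0.29) was the third, while the list as a whole gave camera adjusted p = 0.103 and 0.266 (adjusted p = 0.836 and 0.817 with an estimated correlation). Atf5, Nupr1 and Slc7a5 were singled out after their values were seen.

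Of the genes that flank Ftsj1 on chromosome X, 4 were measured in total mRNA. The glutamine transporter Slc38a5 was at -0.83 (SE 0.292, adjusted p = 0.380, edgeR) and the sterol isomerase Ebp at -0.47 (SE 0.141, adjusted p = 0.199, edgeR), and in ribosome-contained mRNA at -0.76 (adjusted p = 0.391, edgeR) and -0.30 (adjusted p = 0.530, edgeR). With edgeR 0 of the 4 passed over all rows, and adjusted over the list alone these 2 fell in total mRNA. In ribosome-contained mRNA 0 of 3 passed with edgeR, over all rows or adjusted over the list alone, and the list gave camera adjusted p = 0.134 (adjusted p = 0.581 with an estimated correlation). Pcsk1n was at 0.01 and 0.07 in total and ribosome-contained mRNA, and Rbm3 at -0.40 (SE 0.494, adjusted p = 0.881, edgeR) in total mRNA, where 3 of the 4 were negative with a median of -0.43. In total mRNA the list gave camera adjusted p = 0.0744 (adjusted p = 0.593 with an estimated correlation) and passed without WT replicate 1 (camera adjusted p = 0.00623). These 4 genes were named after their values were seen.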
